A study of Mus musculus with 5 samples.

How the data were processed

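RNA was measured by sequencing in 5 libraries of neurospheres grown from the hippocampus of newborn C57BL/6 mice, 3 with 1 floxed copy of Arid1b (heterozygous) and 2 from littermate controls, all carrying hGFAP-Cre. Per the labels' protocols, cells of a mouse were dissociated with trypsin, plated in wells with B27, 20 ng/ml FGF-2 and 20 ng/ml EGF, and harvested as neurospheres on day 7. Per the labels, RNA was extracted with Trizol and libraries were made with an NEBNext Ultra RNA kit and sequenced on an Illumina HiSeq X instrument. The labels do not say whether each library came from a separate mouse, so the p-values measure the spread between these libraries, which may in part be technical.

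Per the submitters' processing notes, the authors used STAR, DESeq2 and the genome build mm10. Versions, the gene annotation, the counting tool and whether counting used the strand are not given in the sources used here. The deposited table holds 54532 genes. The deposited values per library are a normalized signal, which the authors made by dividing read counts per gene by 1 size factor per library, as the whole reads recovered from them show. The deposited table also holds the authors' log2 fold change, heterozygous over control. Its standard error and Wald statistic are used here only as a score that the authors deposited. The authors' p-value and adjusted p-value complete the deposited table, which is a DESeq2 result by its column headers.

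The low values of each library were whole multiples of the value of 1 read, so the reads could be recovered. With a tolerance of 0.001 read, 100% of the values came out whole. Recovered reads numbered 19833803 and 25494722 in control replicates 1 and 2, and 21136608, 25167981 and 23460074 in heterozygous replicates 1, 2 and 3. Between 24961 and 25941 genes had at least 1 read. Chi-square values per gene between libraries of 1 group were 8.07 to 19.33 among heterozygous libraries and 117.92 between the controls, so no pair agreed within sampling noise and none was treated as a repeat deposit of another. This does not show that the libraries came from separate mice.

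The comparison was heterozygous against control, 3 against 2 libraries. Values were taken as log2(normalized count + 1), since the deposited values are not raw counts, and tested with limma (version 3.58.1, R 4.3.3) with an intensity trend in the variance, over the 16411 genes with a mean of at least 10 across the 5 libraries. Fold changes are on this log2 scale, which understates the change of low genes. Tests were two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Single values per library are given without a test. Gene coordinates are 1-based positions on mm10 from the GENCODE annotation. No library column of the table was left unused.

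Of 33 gene lists fixed before the data were examined, the sex-linked genes served only as a check per library and 2 lists had fewer than 4 tested members. The other 30 were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists. The tests of each list were repeated with the correlation estimated from these libraries and with fry, which asks whether a list's genes move, on balance, one way. Counts of members past the threshold are given over all genes tested and adjusted over the list alone. The lists were general markers and pathway genes, none chosen on these libraries, and some genes stand in more than 1 list.

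Genes named in the text followed a rule that was also fixed before the data were examined. It took Arid1b with Arid1a, its alternative in the same complex, and Smarca4, the catalytic subunit. It also took the 12 largest rises and the 12 largest falls among genes past the threshold with non-overlapping groups and a mean of at least 50, leaving out predicted genes, pseudogenes, sex-linked genes and haemoglobin genes. Up to 4 members of each list with the smallest p and the sex-linked genes completed it. Members beyond these 4 are named in the text as called members of their list, after their values were seen. Some genes that the rule takes are not reported here.

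The method was tested on simulated data for heterozygous against control, with 200 of 16411 genes changed in each of 10 runs. limma called 1.6% of genes changed 1.5-fold, 22.8% of those changed 2-fold, 75.6% at 4-fold and 92% at 8-fold, and 0.052% of unchanged genes. camera called 10 of 10 simulated lists of 20 genes shifted 2-fold and 0 of 300 unshifted lists. The simulated genes were drawn independently, while correlations estimated within the lists reached 0.973 (G2 and M phase genes). The simulation therefore does not measure false calls of lists whose genes move together. Each simulated gene also had the same spread in both groups. In the data the controls differed more, by a chi-square value per gene of 117.92 against 8.07 to 19.33 among heterozygous libraries. The simulated rates for single genes may therefore not hold for these libraries.

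Alternatives were pseudocounts of 0.5 and 5, no filter, a mean of at least 50, quantile normalization, TMM factors, robust variance estimates, library weights, a threshold of 0.1, the replicate number as a block, and leaving out each library. edgeR's quasi-likelihood test (version 4.0.16) and DESeq2 (version 1.42.0) were run on the recovered reads, where they called 409 and 2325 genes. With 1 control left out, a fit takes the spread from the heterozygous libraries alone. The controls differed more, by a chi-square value per gene of 117.92 against 8.07 to 19.33. The p-values of such fits therefore understate the spread between controls. Removing trends with GC content, gene length and level (mgcv 1.9.3) was added after seeing the data. GC content and length were known for 16396 of the 16411 genes. Genes that share reads with close relatives, such as the Ifit and Oas families, and genes that overlap another gene on the other strand are uncertain, since the handling of such reads is not given.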

Results

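Neurospheres, floating clusters of neural stem and progenitor cells with their progeny, were grown from newborn mouse hippocampus and compared by RNA sequencing between 3 libraries heterozygous for a floxed Arid1b allele and 2 littermate control libraries. Arid1b encodes a subunit of the BAF chromatin-remodelling complex, and the hGFAP-Cre transgene present in all 5 libraries is active in neural progenitors. Recovered depth ran from 19833803 to 25494722 reads per library. The comparison asks which genes differ in expression when 1 copy of Arid1b is targeted. The heterozygous libraries lay close together, with correlations across genes of 0.9884 to 0.9893. The 2 controls correlated at 0.9521 across genes, and control replicate 1 lay farthest from the heterozygous libraries (0.9267 to 0.930), while control replicate 2 correlated with them at 0.9708 to 0.9744. Genes are not independent replicates, so these values describe the libraries only. Reads of Xist and of 4 Y-linked genes showed heterozygous replicate 2 to differ in sex from the others, with 36851 Xist reads and 0 reads of each Y-linked gene, whereas the other 4 libraries held reads of all 4 Y-linked genes.

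Arid1b was lower in every heterozygous library than in both controls, without passing the test. Arid1b (ENSMUSG00000069729, chromosome 17 from 4994332 to 5347656, + strand) had normalized counts of 1510 and 1730 in the controls and 1102, 1145 and 1003 in the heterozygous libraries. The means were 1620 ± 155 (SD, n = 2) and 1083 ± 72.6 (SD, n = 3), a log2 fold change of -0.58 (SE 0.14, limma adjusted p = 0.0701). The authors' deposited table gave a log2 fold change of -0.56 with an adjusted p of 0.020. In limma the gene's log2 fold change was -0.677 without control replicate 1 and -0.481 without control replicate 2. Gene-level counts do not show whether the floxed exon was lost. Arid1a, which encodes the alternative to the Arid1b subunit in the complex, had a log2 fold change of -0.22 (SE 0.13, limma adjusted p = 0.330). That of Smarca4, the catalytic subunit, was 0.26 (SE 0.23, limma adjusted p = 0.505). The Smarca4 value became -0.14 without control replicate 1 and 0.66 without control replicate 2. Of the 30 BAF complex subunits tested, Actl6b, the neuronal actin-like subunit, rose (log2 fold change 1.12, adjusted p = 0.0486), Bcl7a fell (-0.85, adjusted p = 0.0410), and 28 did not pass. Adjusted over the list alone, 1 rose and 3 fell. The camera adjusted p of the list was 0.455. Its median log2 fold change was -0.055, and it was -0.215 without control replicate 1 and 0.132 without control replicate 2.

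Across the transcriptome, 311 genes rose and 155 fell in heterozygous neurospheres, 279 and 99 of them by more than 2-fold. Car9, Vegfa, Bnip3 and Pdk1, of the fixed list of hypoxia and glycolysis genes, were 4 of the 12 largest falls among called genes with a mean of at least 50, to which the rule for named genes was limited. The fall with the smallest adjusted p was that of Slc16a3, a lactate exporter, at 1563 ± 423 normalized counts in controls (SD, n = 2) and 32.1 ± 6.75 in heterozygous libraries (SD, n = 3), a log2 fold change of -5.55 (SE 0.28, limma adjusted p = 0.0092). Under the same limit, the largest rises were Steap4, a metalloreductase, from 10.97 ± 2.36 to 167 ± 15.1 (log2 fold change 3.82, SE 0.27, adjusted p = 0.0227), and the chemokine Ccl2, from 8.33 ± 3.55 to 125 ± 39.7 (3.76, SE 0.40, adjusted p = 0.0258). Other large rises were Isg15, Ifit1, Thbs2, Aldh1a3, Nefm, Ackr4, Kcng4, Nefl, Cyp24a1 and Il6ra, with log2 fold changes from 2.28 (Il6ra) to 3.44 (Isg15). Aldh1a3 makes retinoic acid and Cyp24a1 breaks down vitamin D. Other large falls were Ndufa4l2, Car9, Mgarp, Bmp4, Fa2h, Vegfa, P4ha2, Bnip3, Prelid2, Pdk1 and Ero1l, with log2 fold changes from -2.24 (Ero1l) to -6.02 (Ndufa4l2). Ndufa4l2 had normalized counts of 513 and 68.6 in the controls and 5.32, 0 and 2.92 in the heterozygous libraries, so its fold depends on the pseudocount. Several of these folds depend on control replicate 1. Without it, the log2 fold changes of Thbs2, Aldh1a3, Nefm and Ackr4 were 1.899, 1.939, 1.921 and 1.851, and those of Ndufa4l2, Car9, Bmp4, Fa2h, Vegfa, P4ha2, Bnip3, Prelid2 and Ero1l were -4.58, -3.85, -3.40, -2.41, -2.43, -2.08, -1.80, -1.70 and -1.57. Without control replicate 2, the rises of the same genes were 3.19 (Nefm) to 3.85 (Thbs2) and the falls -2.90 (Ero1l) to -7.46 (Ndufa4l2). Without heterozygous replicate 2, Ndufa4l2 was at -5.25 and Mgarp at -4.48. Nefl and Nefm overlap on opposite strands of chromosome 14, as do Ndufa4l2 and Shmt2 on chromosome 10, Ackr4 and Acad11 on chromosome 9, and Cyp24a1 and Pfdn4 on chromosome 2, and Ccl2 and Bmp4 each overlap a predicted gene, so their reads may be shared.

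In all 466 called genes the groups did not overlap, and the authors' deposited table called all 311 and 155 in the same direction. That table comes from the same libraries and called 1101 genes higher and 1045 lower, so it is not independent support. The groups also did not overlap for 46.7% of tested genes, where random labels give 20% for a single gene. Genes move together, so that share is not a test of genotype. At an unadjusted p under 0.05, limma gave 4286 genes where 821 were expected. Without heterozygous replicate 1 or 2 only Slc16a3 passed (limma adjusted p = 0.0491 and 0.0483), and without heterozygous replicate 3 no gene did. At an unadjusted p under 0.05 these fits gave 2355, 2586 and 2681 genes. They leave 2 libraries in each group, so the spread between the controls weighs more. The lost calls therefore do not show dependence on 1 heterozygous library. All 466 called genes kept their sign with any 1 library left out. Non-overlapping groups make this certain, so it is no further support. No member of any list described here passed over all genes when 1 heterozygous library was left out, while list medians stayed at 1.302 to 1.405 for neuron markers, -1.086 to -0.975 for hypoxia genes and 1.331 to 1.504 for interferon genes.

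**Figure D1:**
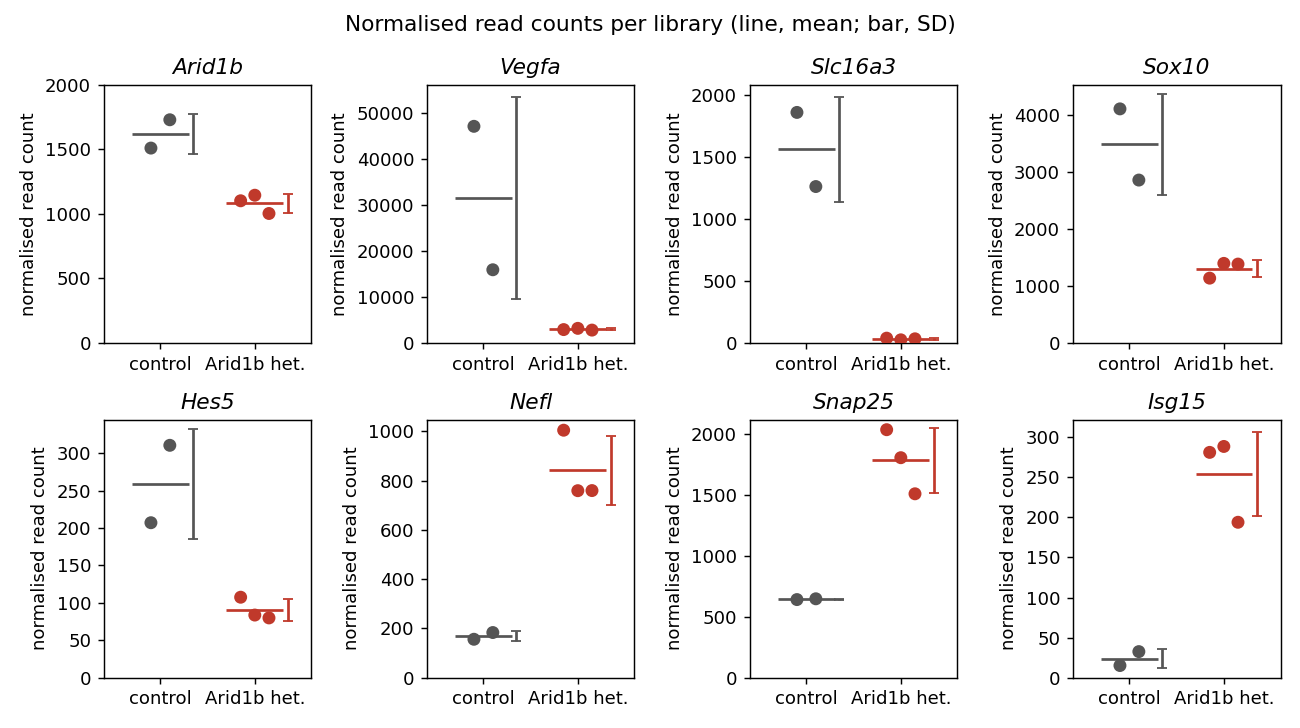
Normalized counts of 8 genes in each library (vertical axis, linear from 0), with dots for the 2 control and 3 heterozygous libraries, a line at each group mean and a bar of 1 SD. Arid1b lay at 1510 and 1730 in the controls and between 1003 and 1145 in the heterozygous libraries, and Vegfa at 47150 and 15924 against 2791 to 3170.

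Genes of hypoxia and glycolysis were lower in heterozygous neurospheres. Of 22 tested, 8 fell, none rose and 14 did not pass (18 fell adjusted over the list alone), with a median log2 fold change of -1.02 (camera adjusted p = 8.04e-12, and adjusted p = 0.358 with an estimated correlation). Vegfa, the angiogenic growth factor (chromosome 17 from 46016993 to 46032369, - strand), went from 31537 ± 22080 normalized counts in controls (SD, n = 2) to 2954 ± 195 (SD, n = 3), a log2 fold change of -3.21 (SE 0.42, limma adjusted p = 0.0322) that was -2.43 without control replicate 1 and -4.00 without control replicate 2. Pdk1, which inhibits pyruvate dehydrogenase, had a log2 fold change of -2.32 (SE 0.26, adjusted p = 0.0258) and Pfkl, a phosphofructokinase, of -2.03 (SE 0.16, adjusted p = 0.0227). Egln3, Hk2, Bnip3, Ankrd37 and Car9 were the others called. Car9, a carbonic anhydrase, was 4755 in control replicate 1 and 466 in control replicate 2, against 26.7 to 37.3 in heterozygous libraries, and its log2 fold change of -5.52 was -3.85 without control replicate 1 and -7.20 without control replicate 2. The list's median was -0.68 without control replicate 1 and -1.34 without control replicate 2. It differed by 0.556 between the controls, higher in control replicate 1.

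Neuronal genes were higher. Of 20 neuron markers, 12 rose, none fell and 8 did not pass (17 rose adjusted over the list alone), with a median log2 fold change of 1.36 (camera adjusted p = 8.04e-12, and adjusted p = 0.358 with an estimated correlation). The neurofilament gene Nefl rose from 170 ± 19.3 to 841 ± 142 normalized counts (log2 fold change 2.30, SE 0.19, limma adjusted p = 0.0227), the vesicular glutamate transporter Slc17a7 from 442 ± 31.1 to 1440 ± 149 (1.70, SE 0.15, adjusted p = 0.0248), and Snap25, of the synaptic vesicle fusion machinery, from 643 ± 4.56 to 1781 ± 263 (1.46, SE 0.16, adjusted p = 0.0258). Of 25 synaptic genes 8 rose and 17 did not pass (15 rose and 1 fell adjusted over the list alone; camera adjusted p = 2.18e-05, and adjusted p = 0.5 with an estimated correlation). They included the NMDA receptor subunit Grin2a (1.53, SE 0.23, adjusted p = 0.0396) and the AMPA receptor subunit Gria4 (0.80, SE 0.13, adjusted p = 0.0427). Among 14 intermediate progenitor and granule neuron lineage genes, Neurod6, Tbr1, Neurod1, Eomes and Igfbpl1 rose, Sox4 fell and 8 did not pass (8 rose and 2 fell adjusted over the list alone; camera adjusted p = 0.0013, adjusted p = 0.358 with an estimated correlation, and 0.0503 without control replicate 2). Neurod1, a neurogenic transcription factor, went from 152 ± 54.1 to 513 ± 71.7 (1.78, SE 0.26, adjusted p = 0.0375), and Sox4 from 8966 ± 315 to 4645 ± 234 (-0.95, SE 0.12, adjusted p = 0.0303). Of 17 GABAergic interneuron lineage genes, Calb1, Sp8 and Maf rose and 14 did not pass (12 rose adjusted over the list alone; camera adjusted p = 7.45e-07, and adjusted p = 0.358 with an estimated correlation). Without control replicate 1, list medians were 1.193 for neuron markers, 0.552 for synaptic, 0.761 for intermediate progenitor and 1.107 for GABAergic lineage genes. Without control replicate 2 they were 1.434, 0.998, 1.039 and 2.066.

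Stem cell and glial markers were mostly lower. Fold changes were positive for 5 of 22 stem cell markers, 4 of 19 oligodendrocyte lineage genes and 5 of 20 astrocyte markers. Among these, the stem cell marker Tnc (1.40, limma adjusted p = 0.0758) and the oligodendrocyte lineage gene Pdgfra (0.41, limma adjusted p = 0.163) did not pass. Of 22 neural stem cell and radial glia markers, 3 fell, among them Fgfr3 and Hes5, and 19 did not pass (4 rose and 10 fell adjusted over the list alone), with a median log2 fold change of -0.49 (camera adjusted p = 0.00193, and adjusted p = 0.358 with an estimated correlation). Fgfr3, a fibroblast growth factor receptor, went from 3963 ± 560 to 1928 ± 131 normalized counts (-1.03, SE 0.14, limma adjusted p = 0.0353), and Hes5, a Notch effector, from 259 ± 73.2 to 90.4 ± 15.0 (-1.49, SE 0.27, adjusted p = 0.0475). Of 19 oligodendrocyte lineage genes, Sox10 and Bmp4 fell and 17 did not pass (12 fell adjusted over the list alone; median -1.27, camera adjusted p = 1.47e-05, adjusted p = 0.358 with an estimated correlation). Sox10, the lineage's transcription factor, went from 3490 ± 885 to 1308 ± 146 (-1.40, SE 0.19, adjusted p = 0.0355), and Bmp4 from 318 ± 249 to 14.4 ± 9.93 (-4.29, SE 0.69, adjusted p = 0.0410; -3.40 without control replicate 1 and -5.19 without control replicate 2). The oligodendrocyte list's median was -0.70 without control replicate 1 and -1.26 without control replicate 2. Of 20 astrocyte markers, Fgfr3, Aqp4 and Atp1b2 fell and 17 did not pass (3 fell adjusted over the list alone; camera adjusted p = 0.00193, adjusted p = 0.5 with an estimated correlation, and 0.0566 without control replicate 1). Aqp4, the water channel, went from 5671 ± 297 to 2277 ± 620 (-1.35, SE 0.22, adjusted p = 0.0427). Of 17 Notch pathway genes, the ligand Jag1 rose (1.23, adjusted p = 0.0258), Dll3 (-1.82, adjusted p = 0.0375) and Hes5 fell, and 14 did not pass (1 rose and 5 fell adjusted over the list alone). The camera adjusted p of the Notch list was 0.0643, and 0.0447 without heterozygous replicate 1. Without control replicate 1, list medians were -0.411 for stem cell markers, -0.263 for astrocyte markers and -0.487 for Notch genes. Leaving out control replicate 2 instead gave -0.632, -0.725 and -0.046.

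**Figure D2:**
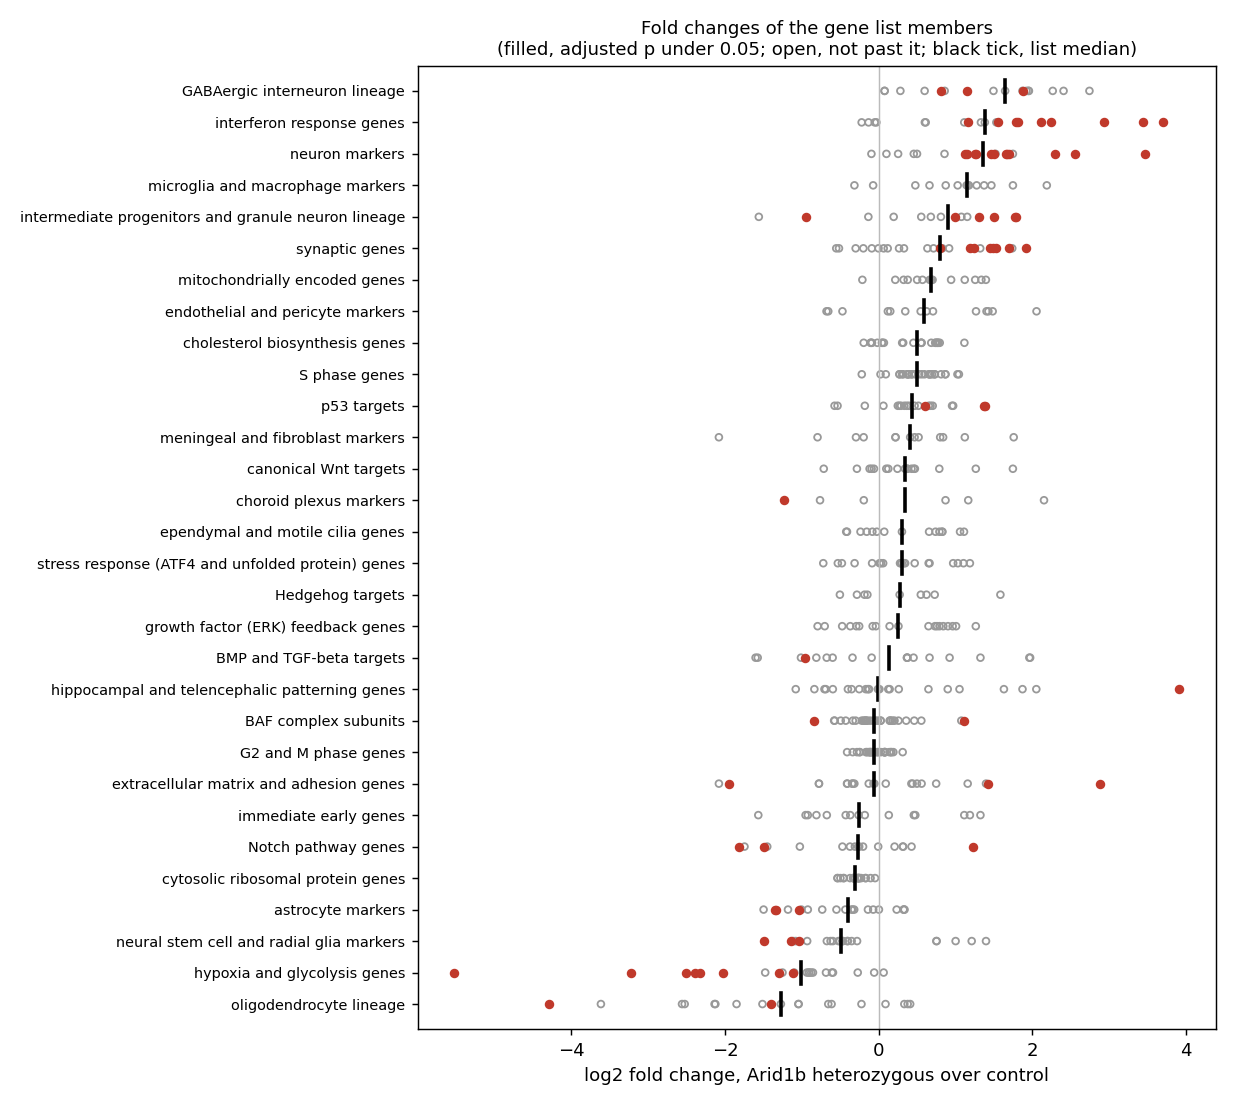
Log2 fold change, heterozygous over control (horizontal axis), of each tested member of 30 gene lists (rows), filled where the limma adjusted p was under 0.05, with a black tick at each list's median. Medians ran from -1.27 for oligodendrocyte lineage genes to 1.64 for GABAergic interneuron lineage genes, and these were -0.70 and 1.11 without control replicate 1.

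Interferon response genes were higher. Of 19 tested, 9 rose, none fell and 10 did not pass (14 rose adjusted over the list alone), with a median log2 fold change of 1.38 (camera adjusted p = 1.13e-08, and adjusted p = 0.358 with an estimated correlation). Isg15, a ubiquitin-like modifier (chromosome 4 from 156199424 to 156200818, - strand), went from 23.8 ± 12.3 normalized counts (SD, n = 2) to 254 ± 52.6 (SD, n = 3), a log2 fold change of 3.44 (SE 0.38, limma adjusted p = 0.0258). Ifi27 went from 970 ± 112 to 2852 ± 220 (1.56, SE 0.14, adjusted p = 0.0258) and Rtp4 from 115 ± 7.57 to 502 ± 71.1 (2.11, SE 0.19, adjusted p = 0.0258). Ifit1, Ifit3, Oas1a, Usp18 and Oasl2 were among the others that rose. The list's median was 1.544 without control replicate 1 and 1.322 without control replicate 2. The Ifit and Oas genes have close relatives, so their counts are uncertain. Of 14 microglia and macrophage markers none passed over all genes or adjusted over the list alone, while the camera adjusted p of the list was 0.0467 (higher; adjusted p = 0.741 with an estimated correlation). It was 0.139 without control replicate 1, 0.218 without control replicate 2, 0.0983 without heterozygous replicate 2 and 0.193 without heterozygous replicate 3. The microglia call was also lost with a mean of at least 50 (0.856), quantile normalization (0.0935), library weights (0.271) and GC, length and level trends removed (0.0535). Summed over the 20 microglia markers of the list, normalized counts were 962 and 848 in the controls and 689, 1363 and 1674 in the heterozygous libraries. Of 20 p53 target genes, Pmaip1 (1.38, SE 0.16, adjusted p = 0.0263), Perp (1.37, SE 0.24, adjusted p = 0.0470) and Mdm2 (0.60, SE 0.11, adjusted p = 0.0489) rose and 17 did not pass (6 rose adjusted over the list alone; camera adjusted p = 0.000654, adjusted p = 0.5 with an estimated correlation, and 0.116 without control replicate 2). The p53 list's median was 0.573 without control replicate 1 and 0.191 without control replicate 2. Mdm2 encodes the p53 ubiquitin ligase, and Pmaip1 and Perp encode cell death factors.

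In the lists of mitochondrially encoded, ribosomal protein, cholesterol biosynthesis, S phase and G2 and M phase genes, none passed over all genes. Of 14 mitochondrially encoded genes 5 rose adjusted over the list alone (camera adjusted p = 9.02e-05, and adjusted p = 0.358 with an estimated correlation). Their share of reads was 2.94% and 2.56% in the controls and 3.34%, 3.35% and 3.82% in the heterozygous libraries. No gene passed, by either count, among 23 cytosolic ribosomal protein genes, 22 cholesterol biosynthesis genes and 28 S phase genes. The ribosomal list was lower (camera adjusted p = 0.0013, adjusted p = 0.741 with an estimated correlation, and 0.432 without control replicate 1). Cholesterol biosynthesis genes were higher (camera adjusted p = 0.0347, and adjusted p = 0.846 with an estimated correlation), with the direction turned without control replicate 1 (adjusted p = 0.601) and the call lost without heterozygous replicate 1 (0.0759) or 3 (0.0522), or with DESeq2 (0.0643). S phase genes were higher (camera adjusted p = 0.0491, and adjusted p = 0.853 with an estimated correlation). Their median log2 fold change was 0.499, but -0.455 without control replicate 1 and 1.482 without control replicate 2. Without heterozygous replicate 3 the camera adjusted p was 0.146. The call was also lost with a pseudocount of 5 (adjusted p = 0.0505), a mean of at least 50 (0.0692), edgeR (0.136), DESeq2 (0.441) and GC, length and level trends removed (0.0535). The median of 28 G2 and M phase genes was -0.06 (camera adjusted p = 0.613). The median was -0.696 without control replicate 1 and 0.611 without control replicate 2. Medians of mitochondrially encoded, cholesterol and ribosomal protein genes were 0.609, -0.087 and -0.059 without control replicate 1. Without control replicate 2 they were 0.613, 0.932 and -0.57.

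The remaining lists did not pass in camera with all 5 libraries. Of 18 BMP and TGF-beta targets, Id3 fell (-0.96, SE 0.14, limma adjusted p = 0.0384) and 17 did not pass (3 rose and 4 fell adjusted over the list alone; camera adjusted p = 0.836, direction lower, with a median of 0.14). Of 22 extracellular matrix and adhesion genes, Lamb1 (1.42, adjusted p = 0.0351) and Thbs2 (2.87, adjusted p = 0.0470; 1.90 without control replicate 1 and 3.85 without control replicate 2) rose, Fbln2 fell (-1.95, adjusted p = 0.0266) and 19 did not pass (3 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.941, direction higher, with a median of -0.06). Of 6 choroid plexus markers, Enpp2 fell (-1.23, adjusted p = 0.0258) and 5 did not pass (2 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.836). Enpp2 is also made by oligodendrocytes. Among 23 hippocampal and telencephalic patterning genes, Wnt3a, a signal of the hippocampal organizer, rose from 0.45 ± 0.64 to 19.9 ± 3.41 normalized counts (adjusted p = 0.0333) and 22 did not pass (3 rose and 2 fell adjusted over the list alone; camera adjusted p = 0.950). With control replicate 1 left out, list medians were 0.233 for extracellular matrix genes and 0.153 for BMP and TGF-beta targets. They were 0.069 for patterning genes and 0.009 for choroid plexus markers. With control replicate 2 left out, the medians were -0.164, -0.116, -0.089 and 0.295 in the same order. No member passed over all genes in the other 8 lists tested. Growth factor feedback genes had 7 that rose and 2 that fell adjusted over the list alone (camera adjusted p = 0.158). Stress response genes had 3 and 1 (0.123) and immediate early genes 2 and 1 (0.736, with a lower direction where fry gave a higher one). Ependymal and motile cilia genes (camera adjusted p = 0.160) had none by either count. Nor had endothelial and pericyte markers (0.248), meningeal and fibroblast markers (0.455), canonical Wnt targets (0.219) or Hedgehog targets (0.455). With control replicate 1 left out, medians were 0.264 for growth factor feedback, 0.157 for stress response, -0.023 for immediate early and 0.499 for ependymal genes. They were 0.889 for endothelial, 0.967 for meningeal, 0.244 for Wnt and 0.005 for Hedgehog genes. With control replicate 2 left out, the medians in the same order were 0.074, 0.55, -0.11, 0.267, 0.359, -0.29, 0.436 and 0.601. Erythroid genes (1 of 10 tested) and Hox genes (0 of 22) had too few tested members.

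**Figure D3:**
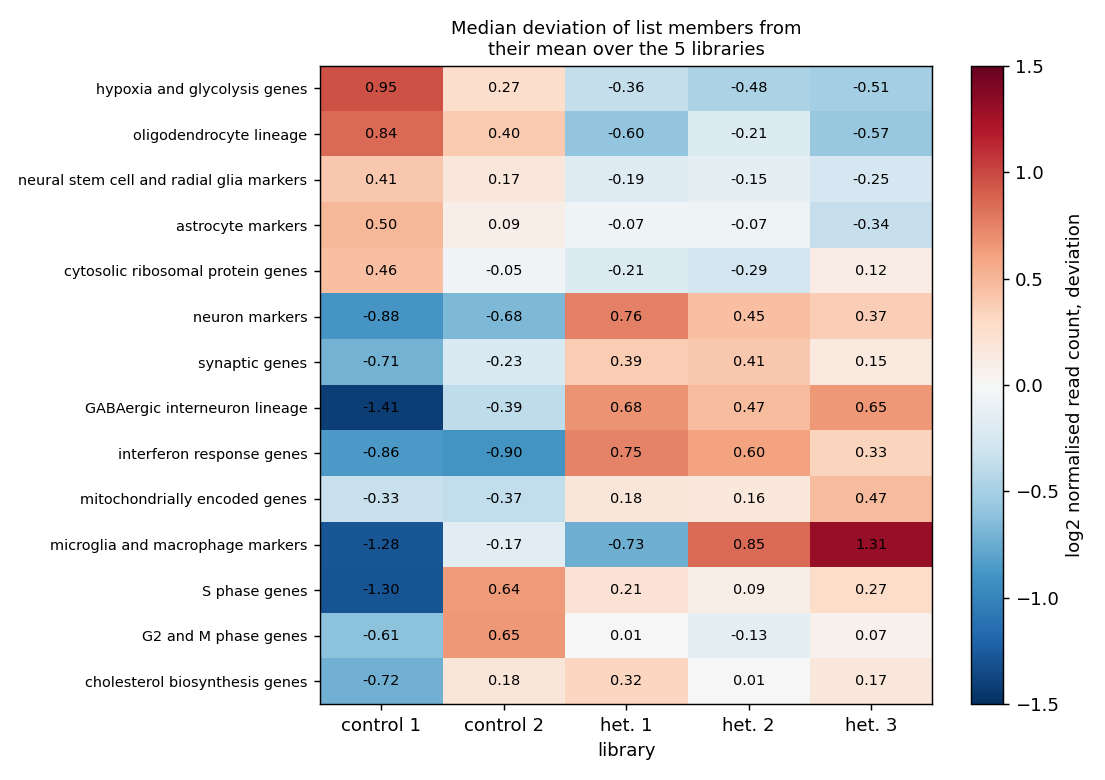
Median deviation from the mean over the 5 libraries (log2, colour) of 14 gene lists (rows) in each library (columns). Neuron markers lay at -0.88 and -0.68 in the controls and at 0.76, 0.45 and 0.37 in the heterozygous libraries.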

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

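The removal of GC, length and level trends was chosen after seeing the data, and the other settings were planned. All 466 called genes kept their sign in every setting in which they were tested (430 of them with a mean of at least 50). Since their groups did not overlap, leaving out 1 library or changing the pseudocount or filter could not turn a sign. Counts of genes higher and lower stayed within 1.5 times of 311 and 155 with another pseudocount, filter or scaling, with edgeR and with robust variance estimates, ranging from 240 to 433 and from 143 to 228. They moved to 1174 and 1151 with DESeq2, 79 and 38 with library weights, and 1104 and 771 at a threshold of 0.1, and to 259 lower (409 higher) with the trends removed. The looser threshold explains its own counts, and the cause of the others was not tested. Leaving out 1 library gave 0 to 4465 genes higher and 0 to 3855 lower. Fits without a control library assume that the remaining control varies like the heterozygous libraries. The labels do not say that replicate numbers pair the libraries, and deviations of same-numbered libraries correlated at 0.028 and -0.040 over 2 pairs. With the replicate block, 0 genes were higher and 1 lower (2450 at an unadjusted p under 0.05). Only the heterozygous group has a replicate 3, so that library did not inform the comparison. The block left little from which to estimate the spread, so the lost calls do not show an effect of pairing.

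Arid1b was lower in all settings. It passed with DESeq2 (-0.589, adjusted p = 0.00729), at a threshold of 0.1 (-0.579) and with the trends removed (-0.624, adjusted p = 0.0430), and ranged from -0.677 to -0.481 with 1 library left out. Its adjusted p ran from 0.00729 to 0.354. The number of lists past camera, 15 of 30, was 12 to 17 in other settings, 0 with an estimated correlation and 8 with fry. fry did not call the oligodendrocyte (0.0565), astrocyte (0.109), p53 (0.0565), synaptic (0.0619), ribosomal (0.396), cholesterol (0.561), S phase (0.651) and microglia (0.396) lists, and called growth factor feedback genes (0.0334). In camera, the S phase call was lost with a pseudocount of 5 (0.0505), a mean of at least 50 (0.0692), edgeR (0.136), DESeq2 (0.441) and the trends removed (0.0535), the cholesterol call with DESeq2 (0.0643), and the microglia call with a mean of at least 50 (0.856), quantile normalization (0.0935), library weights (0.271), the replicate block (0.053) and the trends removed (0.0535). Notch genes passed with no filter (0.0344) and edgeR (0.0334), stress response genes with no filter (0.0435), and endothelial and pericyte markers with the replicate block (0.0493). Leaving out 1 library gave 12 to 17. Robust variance estimates do not enter camera and gave no list result.

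Directions that turned were mostly of lists far from the threshold, given as adjusted p. Patterning genes turned with no filter (0.99), quantile normalization (0.919), edgeR (0.939), the replicate block (0.804) and fry (0.353), extracellular matrix genes with DESeq2 (0.983) and the trends removed (0.999), choroid plexus markers with DESeq2 (0.956), meningeal markers with a mean of at least 50 (0.974), and BMP targets (0.704) and immediate early genes (0.826) with fry. With 1 library left out, adjusted p values of lists that turned ran from 0.409 to 0.992 for patterning genes, 0.139 to 0.996 for extracellular matrix genes, 0.0184 to 0.668 for meningeal markers, 0.0103 to 0.589 for BAF subunits and 0.341 to 0.992 for BMP targets (turned without control replicate 1, 0.745). The S phase list (7.39e-12 to 0.146) and cholesterol genes (1.33e-05 to 0.601) turned without control replicate 1 (S phase 1.17e-08), and G2 and M phase genes (2.18e-15 to 0.921) without control replicate 2 (7.82e-06). Log2 fold changes ran from -0.142 to 0.657 for Smarca4, -0.323 to 2.409 for Tyms, -0.302 to 2.031 for Cdc6 and -0.265 to 1.715 for Rrm2, negative without control replicate 1, and from -0.705 to 0.029 for Ccnb2, -0.712 to 0.147 for Kif23 and -0.714 to 0.211 for Nusap1, positive without control replicate 2. Of other named genes, none turned. The cause was not tested. At this number of libraries, 2-fold changes simulated with the same spread in both groups were called for 22.8% of genes. In that setting smaller changes were mostly not detectable.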

Other observations

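All tests in this part were chosen after the results were seen. The 2 control libraries differed from each other in cell cycle genes. All 28 S phase genes and all 28 G2 and M phase genes were lower in control replicate 1 than in control replicate 2, with median log2 differences of -1.90 and -1.28. Cholesterol biosynthesis genes were also lower in control replicate 1 (median -0.89, 1 of 22 higher), and all 23 cytosolic ribosomal protein genes were higher (median 0.50). Mbp, a myelin protein gene, had 8896 normalized counts in control replicate 1 and 572 in control replicate 2, and Fn1, fibronectin, had 13668 and 2496. In heterozygous libraries Mbp lay between 268 and 484 and Fn1 between 1139 and 1587. These genes were named after their values were seen.

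Heterozygous replicate 3 held 301 Xist reads beside reads of all 4 Y-linked genes, 0.89% of the normalized Xist count of heterozygous replicate 2. Whether these reads came from another library, by index hopping or carry-over, was not tested here.

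The real grouping of the libraries gave 466 called genes, and the highest of the other splits gave 0. It was the only 1 of the 10 splits of 5 libraries into 2 and 3 with as many, and 10 splits are too few for a share under 0.05.

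Hypoxia and glycolysis genes were lower in heterozygous libraries, and control replicate 1 held the highest values for many. Control replicate 2 also lay above all 3 heterozygous libraries for 20 of 22 members. The median gap was 0.681, against a median range of 0.226 among heterozygous libraries. This argues against control replicate 1 alone as the source. The members move together (estimated correlation 0.429), so they are not replicates. Control replicate 2 is 1 library, and for a single gene it would lie above the 3 others with a chance of 25%. Removing GC, length and level trends left the median at -1.016, with 10 members called, while it moved genes by a median of 0.044. Oxygen supply or sphere density differing between wells may contribute and cannot be told apart from genotype, since the labels record neither. The list differed by 0.556 between the controls, while its medians in the heterozygous libraries ranged over 0.144. A lower hypoxia response with loss of 1 Arid1b copy stays open as a hypothesis.

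The list of neuron markers was higher, and those of neural stem cell, astrocyte and oligodendrocyte genes lower with most members not past the threshold (19 of 22, 17 of 20 and 17 of 19), all without a call when the correlation was estimated (adjusted p = 0.358, and 0.5 for astrocytes), the latter 2 also not called by fry (0.109 and 0.0565). Removing GC, length and level trends left the neuron marker median at 1.34, with 12 members called as before. A lower share of oligodendrocyte-lineage cells alone would raise the other classes alike, but the neuron median exceeded the neural stem cell median by 1.847, against 0.737 for the sum of the spreads of both lists (each from its median to a quartile, averaged). More neurons per sphere, or more neuronal expression per cell, may underlie the pattern. Bulk RNA does not separate these, the number of neurons carried over from the dissected tissue was not measured, and the effect of genotype stays a hypothesis.

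Interferon response genes were higher in heterozygous libraries. Control replicate 2 lay below all 3 heterozygous libraries for 17 of 19 members (89.5%), with a median gap of 1.544 against a median heterozygous range of 0.469, which argues against control replicate 1 alone. Here too the members are not replicates, and control replicate 2 is 1 library. In heterozygous replicate 1 the median log2 difference from the controls was 1.682 for interferon genes and -0.112 for tested microglia markers. This argues against more microglia as the source of the rise in that library. The 20 microglia markers summed to 688.8 normalized counts there, below both controls (962.4 and 847.8), but a sum weighs high genes most. By median deviation from the mean over the 5 libraries, tested markers in this library (-0.734) lay between control replicates 1 (-1.278) and 2 (-0.165). In heterozygous replicates 2 and 3 the markers summed to 1363.1 and 1673.6, above both controls. Their median log2 differences from the controls were 1.551 and 1.902, against 1.402 and 1.139 for interferon genes. A contribution of microglia there cannot be told apart, since microglia may carry interferon transcripts in an unknown amount. Infection of the cultures, plating and the animals' litter were not tested, and an effect of genotype stays open as a hypothesis.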
